A study of Homo sapiens with 37 samples.

How the data were processed

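The data are 2-colour Agilent arrays of 45015 spots, of which 1639 are controls and 43376 carry genes. For the electron groups the deposited scanner files hold intensity per spot for each dye: mean foreground and median local background, and, per the file headers, signals that the scanner software (Feature Extraction 9.5.3.1) had background-corrected and dye-normalized. For all 37 samples the deposited value table holds log10 of Cy5 over Cy3 from those processed signals. On the 19 electron columns it equals the scanner software's ratio, and exact zeros there mark spots with both channels at a surrogate for dim signal. The ratios were converted to log2. The 18 proton columns have medians of 0 as well, and their scale, centring and direction are taken to be those of the electron columns. The quality flags are per the file headers 0 or 1 for each spot. Zeros make up 8.74% to 24.2% of an electron column and 9.29% to 18.2% of a proton column.

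Per the labels the samples are replicates of a group, but barcodes in the headers of the scanner files show that the samples of an electron group are repeat scans of 2 arrays, with 3 and 4 scans in MCF10A and 3 and 3 in the other lines. The proton columns fall into 2 sets of 3 by correlation in each line. In MCF7 after protons, for example, r was 0.636 to 0.823 within a set and 0.291 to 0.333 between sets, and in MCF10A after electrons 0.835 to 0.857 within an array and 0.758 to 0.792 between arrays. Proton sets were therefore treated as arrays, which is an inference. Scans were averaged per array, a choice made after the files were seen, and n counts arrays. The label protocol names untreated MCF10A as the control of all samples whereas other label fields name the sample's own line, and marker genes settled it for the own line on the electron arrays. The proton arrays have no intensities to check, but their ratios argue against an MCF10A control for MCF7 and MDA-MB-231. In MCF7 after protons ESR1 stood at -0.098, KRT5 at 0 and VIM at -0.31. In MDA-MB-231 KRT5 stood at 0.012 and CDH1 at 0.93. Untreated log2 signals of KRT5 were 16.45 in MCF10A, 1.87 in MCF7 and 1.67 in MDA-MB-231. An MCF10A control would put its ratio far below 0. Electron arrays of each line had their own slides and scan day, 5 slides and 3 days in all, so line and slide cannot be told apart, and beam and batch cannot be told apart either.

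Probes were named from the accession they carry (23434), a current symbol (2317) or an older synonym (1043), and 14206 kept the name in the file. This gave 30990 genes, of which 17519 have a current symbol and 7513 more than 1 probe. A gene is read from its brightest probe. Genes tested were those well above background in either channel on at least 50% of the line's electron scans: 19006 in MCF10A, 21164 in MCF7 and 24017 in MDA-MB-231, and the same genes for protons. Differences between lines were tested on genes that passed in either line. These were 22316 for MCF7 and MCF10A, 24672 for MDA-MB-231 and MCF10A, and 25151 for MDA-MB-231 and MCF7. A gene in such a difference may therefore be dim in the other line. Probe positions are on build hg17, and which exon a probe lies in was not analysed.

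Electron effects and electron line differences come from the scanner intensities: normexp background correction with an offset of 50, loess within arrays, then limma lmFit and eBayes with a mean per line. Proton effects, proton line differences and beam differences come from the table, with a mean per line and beam. The 2 sources differ in background correction, offset and normalization, and in their values (MDM2 in MCF10A after electrons was 1.08 from the scanner signals and 3.17 in the table), so values of the 2 sources are not compared with each other. Residual degrees of freedom were 3 and 6. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least 1.5-fold, over 15 comparisons. Only genes tested were used to estimate the spread, and exact zeros were kept, both chosen after the files were seen.

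Before the data were examined 22 gene lists of 433 genes were fixed, 430 of them on the array (ACER2, KRT6A and NDUFA4 are not): p53 targets, G2/M and mitosis, DNA replication, homologous recombination and Fanconi repair, non-homologous end joining, histones, NF-kB targets and inflammatory cytokines, interferon response, matrix remodelling, NRF2, ATF4 and unfolded protein, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, keratinocyte differentiation, estrogen response, luminal, basal and mesenchymal markers, ribosomal proteins, mitochondrial respiration, and senescence and lysosome. Lists were tested by limma's camera with its preset correlation of 0.01, adjusted over the lists of a comparison, 330 results in all, of which 110 passed. In the report, "range" is the lowest and highest adjusted p of that list over the alternative processings, and "estimated correlation" is camera with the correlation estimated from the residuals, which kept 5 of the 110. Counts "over the list alone" adjust p within the list.

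The genes named are, per effect, the 4 highest and 4 lowest called with a symbol and the same sign on every scan, the 2 largest of each list with at least 3 called, and CDKN1A, MDM2, GDF15, TP53, CCNB1 and RAD51 whatever their test. Per difference they are the 4 highest, 4 lowest, 2 per list and CDKN1A. This gave 515 gene results, 489 past the threshold, and the report passes over most of those that were dim, had probes that disagreed or lost their call with 1 array left out. Genes outside the rule, such as CXCL2 in MCF10A after protons and IER3, were chosen after values were seen.

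With ratios shifted by a known amount in simulated data the MCF10A electron test found 97.0% of genes at 1.6-fold and 98.5% at 2-fold, and the MCF10A proton test 68.7% and 88.1%. For the MCF10A beam difference it was 59.7% and 86.6%, and for the electron difference of MCF7 and MCF10A 82.1% and 97.0%. False calls were 1, 2, 3 and 2. The simulated noise was independent between genes and held no dye or GC bias. These counts therefore do not measure false calls on the real arrays. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.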

Results

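Transcript levels were measured in 3 human breast cell lines 24 h after a dose of 9 Gy given as an electron or a proton beam. MCF10A is a non-tumorigenic epithelial line, MCF7 is an oestrogen receptor positive tumour line, and MDA-MB-231 is a receptor negative, mesenchymal-like tumour line known to carry mutant p53. Each array set amplified RNA of irradiated cells (Cy5) against RNA of untreated cells of the same line (Cy3), so every ratio is irradiated over untreated. The untreated channel of the electron arrays matched the named line: in MCF7 the log2 signal of ESR1, the oestrogen receptor, was 11.34 and that of KRT5, a basal keratin, 1.87, while MCF10A had KRT5 at 16.45 and ESR1 at 2.72. MDA-MB-231 had VIM, a mesenchymal filament, at 16.76 and CDH1, an epithelial cadherin, at 2.57.

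The 37 deposited samples were 7 of MCF10A after electrons and 6 of each other line and beam. By header barcodes those of the electron groups were repeat scans of 6 arrays, 2 per group. Those of the proton groups were taken as repeat scans of 2 arrays per group from their correlations alone, which is an inference. Scans were averaged, and n = 2 arrays in every group, for protons on that inference. Signal stood above background as follows: in the electron groups, the only ones with scanner files, 55.9% to 58.4% of gene spots were well above background in Cy3 for MCF10A, 63.5% to 67.6% for MCF7 and 71.4% to 73.1% for MDA-MB-231. Cy5 had 58.6% to 64.6%, 61.0% to 68.6% and 76.0% to 79.1%. All irradiated samples carried the same dye, so a dye bias of a gene cannot be told apart from its response. The p-values measure only the spread between these arrays, which may be technical, and "±" below is the standard error of the limma fit unless a standard deviation is named. That error pools the spread of all groups in a fit. It can understate the spread of a group whose arrays differ, as in MCF7 after protons, and overstate that of other groups.

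After electrons, MCF10A raised its p53 targets. GDF15, a stress cytokine, rose by 2.07 ± 0.054 log2 (4.18-fold, n = 2), CDKN1A, the p21 inhibitor of cyclin-dependent kinases, by 1.55 ± 0.046 (2.94-fold) and MDM2, the ubiquitin ligase that degrades p53, by 1.08 ± 0.15, with arrays at 0.69 and 1.47. Among 35 tested p53 targets 18 rose and none fell, with a list median of 0.60. The largest rises were those of WNT6, a secreted growth factor (4.81 ± 0.095, 28.1-fold), COX6A2, a muscle subunit of cytochrome oxidase (4.67 ± 0.070), GPR153, an orphan receptor (4.65 ± 0.038), and SOX3, a neural transcription factor (4.63 ± 0.079). They belong to 151 genes over 8-fold higher on these arrays, whose probes had a median GC content 31.7 percentage points above that of all tested genes, so their rise may be technical, although the COX6A2 probe has only 55.0%. Among the largest falls were ALYREF, an mRNA export adaptor (-1.57 ± 0.029), EEF1A1, the translation elongation factor (-1.56 ± 0.030), and KPNB1, a nuclear import receptor (-1.46 ± 0.030). With median centring EEF1A1 (-0.23) and KPNB1 (-0.54) were not called, and with scale normalization none of the genes named here but MDM2 was, CDKN1A standing at 2.72 and WNT6 at 8.91.

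The CDKN1A probe lay at chromosome 6, 36762684 to 36762743 and the MDM2 probe at chromosome 12, 67489279 to 67489338 on genome build hg17. Cholesterol synthesis had 4 of 17 tested genes lower and none higher, a fall that turned into a rise with median centring. MSMO1 and IDI1, a sterol oxidase and an isomerase of that pathway, fell by 1.01 ± 0.072 and 0.77 ± 0.037 log2. A second MSMO1 probe stood at -0.16. Immediate early genes split: 5 fell, among them EGR1, FOS and MYC (another MYC probe at 0.032), and 2 rose, JUN (1.72 ± 0.090) and IER3, and the list did not pass (adjusted p = 0.24). Mitochondrial respiration had 7 genes higher, such as the complex I and IV subunits NDUFA1 (1.30 ± 0.055) and COX6C (1.22 ± 0.050), and 2 lower (adjusted p = 0.31). The DNA replication list did not pass (1 higher, 3 lower, adjusted p = 0.37), although MCM6, a replicative helicase subunit, fell by 1.19 ± 0.047, not called with median centring (-0.49). Of the genes given with values here, JUN, NDUFA1, COX6C and MCM6 were not called with scale normalization, and MSMO1 and IDI1 not with median centring. G2/M and mitosis genes did not pass, with none called.

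In total 1110 genes were higher and 544 lower in MCF10A after electrons (limma). By camera the p53 targets rose at adjusted p = 9.6e-10 (range 7.0e-15 to 0.00014), adjusted p = 0.61 with an estimated correlation, and the cholesterol list fell at adjusted p = 0.00038 (range 1.1e-05 to 0.93), adjusted p = 0.60 with an estimated correlation. Both lists had the same counts when adjusted over the list alone. WNT6, SOX3 and the p53 target BBC3 have other probes with ratios near 0 (0.0063, -0.026 and 0.096), and the rises of CDKN1A and MDM2 were 0.44 and 0.27 on other probes. The higher share depended on scaling: 5019 of 5050 called genes were higher with median centring and 277 of 305 with scale normalization.

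After electrons, MCF7 combined rising p53 targets and immediate early genes with falling replication and repair genes. GDF15 rose by 2.18 ± 0.054 log2 (4.53-fold, n = 2), CDKN1A by 1.40 ± 0.046 (2.63-fold) and TP53INP1, a p53-induced autophagy protein, by 1.96 ± 0.042. The early transcription factors EGR2 (2.77 ± 0.035), EGR4 (2.67 ± 0.040), EGR3 (2.33 ± 0.029) and the stress factor ATF3 (2.78 ± 0.040) were among the largest rises. RRM2, a subunit of ribonucleotide reductase, fell by 1.75 ± 0.036, CDC45, a part of the active replicative helicase, by 1.68 ± 0.032 and the crosslink repair gene FANCA by 1.11 ± 0.045. MAPK4, an atypical kinase (-2.76 ± 0.031), CEMIP, a hyaluronan-degrading protein (-2.71 ± 0.041, another probe at -0.079), and the transcription factor ZNF652 (-2.37 ± 0.062) were among the lowest ratios. With scale normalization GDF15 (1.10), CDKN1A (0.70), TP53INP1 (0.98), CDC45 (-0.84) and FANCA (-0.56) were not called.

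By list, 24 of 34 tested p53 targets rose and none fell, and 14 of 16 immediate early genes rose. DNA replication had 21 of 30 genes lower and homologous recombination and Fanconi repair 13 of 20, including BRCA1 (-1.05 ± 0.028) and RAD51 (-0.59 ± 0.050), a recombinase whose fall was -0.56 and not called without array 2. Interferon response had 11 of 27 genes higher, led by IFI27 (1.79 ± 0.049), a mitochondrial effector, and IFIT1 (1.74 ± 0.059), which binds viral RNA. NF-kB targets had 6 of 13 higher, among them its own inhibitor NFKBIA (1.26 ± 0.033), and matrix remodelling 6 higher and 1 lower of 18. Cholesterol synthesis had 8 of 17 lower (MSMO1 -1.38 ± 0.072, another probe at -0.22) and mitochondrial respiration 5 of 17 lower, though that list turned to higher with median centring. G2/M and mitosis did not pass as a list (1 higher, 4 lower, adjusted p = 0.22), and CDK1, the mitotic kinase, fell by 0.87 ± 0.029, not called with median centring (-0.37). With scale normalization BRCA1 (-0.53), NFKBIA (0.64) and MSMO1 (-0.69) were not called.

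In MCF7 after electrons 1259 genes were higher and 1606 lower (limma). By camera the p53 targets gave adjusted p = 6.3e-11 (range 5.5e-14 to 5.7e-06), adjusted p = 0.34 with an estimated correlation; the immediate early genes adjusted p = 1.8e-08 (range 6.5e-11 to 9.3e-05), adjusted p = 0.088 with an estimated correlation; DNA replication adjusted p = 1.9e-10 (range 5.5e-14 to 4.4e-06), adjusted p = 0.088 with an estimated correlation; homologous recombination adjusted p = 1.3e-06 (range 9.9e-09 to 0.00097), adjusted p = 0.28 with an estimated correlation. Interferon response gave adjusted p = 4.6e-07 (range 2.6e-08 to 0.00017), adjusted p = 0.28 with an estimated correlation, NF-kB targets adjusted p = 9.9e-05 (range 5.2e-05 to 0.020), adjusted p = 0.28 with an estimated correlation and matrix remodelling adjusted p = 0.037 (range 0.018 to 0.21), adjusted p = 0.40 with an estimated correlation. Cholesterol synthesis gave adjusted p = 0.0031 (range 0.00069 to 0.28), adjusted p = 0.28 with an estimated correlation and mitochondrial respiration adjusted p = 0.00056 (range 4.4e-05 to 0.94), adjusted p = 0.34 with an estimated correlation. With scale normalization 369 genes were called, 123 of them higher, and with median centring 4989 of 5715 were higher.

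After electrons, the genes that changed in MDA-MB-231 included histones. H4C14 fell by 1.54 ± 0.040 log2, H4C8 by 1.48 ± 0.046 and H4C9 by 1.33 ± 0.032, all coding for core histone H4, and H2BC5, for histone H2B, by 1.17 ± 0.12 (n = 2). HES1, a Notch target repressor, rose by 1.30 ± 0.067 (2.46-fold, another probe at 0.16), FOSB, an AP-1 subunit, by 1.09 ± 0.030, and DUSP1, a phosphatase that ends MAP kinase signals, by 1.03 ± 0.035. Histone genes had 9 of 16 lower and none higher, and immediate early genes 4 of 15 higher. DNA replication had 3 of 30 lower, among them MCM6 (-0.68 ± 0.045) and MCM5 (-0.61 ± 0.038), a fall of the list that turned into a rise with median centring. None of these genes was called with median centring (HES1 1.64, H4C8 -1.23, FOSB 1.26), and HES1 (3.08) and MCM6 (-1.56) were not with scale normalization.

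CDKN1A (0.016 ± 0.045), MDM2 (-0.15 ± 0.16) and GDF15 (-0.44 ± 0.053) were not called, and 1 of 33 tested p53 targets was higher (adjusted p = 0.86). Here 105 genes were higher and 149 lower (limma). Camera gave adjusted p = 1.0e-13 (range 2.8e-16 to 1.1e-08), adjusted p = 0.21 with an estimated correlation for histones, adjusted p = 0.0051 (range 0.0023 to 0.34), adjusted p = 0.24 with an estimated correlation for DNA replication and adjusted p = 0.043 (range 0.00052 to 0.32), adjusted p = 0.24 with an estimated correlation for immediate early genes. G2/M and mitosis rose as a list with 1 gene called of median 0.28 at adjusted p = 4.9e-11 (range 5.8e-14 to 0.00012), adjusted p = 0.13 with an estimated correlation, as did interferon response at adjusted p = 1.6e-06 (range 4.2e-08 to 0.00015), adjusted p = 0.24 with an estimated correlation. With median centring 0 genes passed limma, although 5225 had an unadjusted p below 0.05, and scale normalization called 1440, more than the 305 in MCF10A and 369 in MCF7, so the order of the lines by number of genes turned with scaling.

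**Figure D1:**
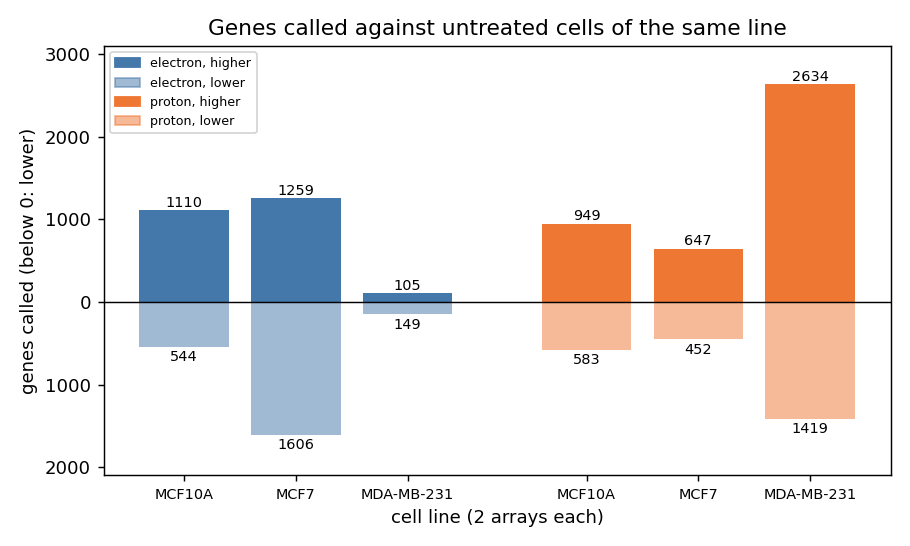
Number of genes called higher (above 0) and lower (below 0) than untreated cells of the same line, by line and beam, with 2 arrays per bar; electron counts are from scanner signals and proton counts from the deposited ratio table. Bars of the 2 beams come from different sources and are to be compared within a beam only, and the order of the electron bars turns with scale normalization.

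After protons, MCF10A again raised its p53 targets. CDKN1A rose by 1.80 ± 0.17 log2 (3.47-fold, n = 2), GDF15 by 1.77 ± 0.27 and MDM2 by 1.56 ± 0.21, while TP53 itself fell by 0.69 ± 0.070. IGFL2, an insulin-like growth factor family member (3.42 ± 0.22, 10.7-fold), TRIML2, a p53-regulated TRIM protein (2.98 ± 0.067), APOBEC3B, a cytidine deaminase (2.88 ± 0.21), and INSL4, a relaxin-like peptide (2.85 ± 0.13), had the highest ratios. PPARGC1A, a coactivator of mitochondrial biogenesis, fell by 2.29 ± 0.071, and NRTN, a neurotrophic ligand, by 2.06 ± 0.15. The cornified envelope protein IVL rose by 2.51 ± 0.33 and the protease KLK7 by 2.19 ± 0.37. CXCL1 and CXCL2, neutrophil chemokines, were at -1.33 and -0.92.

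Of 35 tested p53 targets 27 rose and none fell. NF-kB targets had 7 of 17 lower and 1 higher, the cytokine LIF, and 9 called when adjusted over the list alone. Interferon response had 5 of 24 higher, for example HERC6 (1.18 ± 0.072), and G2/M and mitosis 3 of 30 higher, for example CCNB1, cyclin B1 (0.66 ± 0.049), and HMMR, a spindle protein (0.65 ± 0.040). Histones fell as a list with 1 of 15 called lower (median -0.30) at adjusted p = 0.00091 (range 0.00027 to 0.0060), adjusted p = 0.14 with an estimated correlation. Keratinocyte differentiation had 8 of 17 higher and 2 lower without passing as a list (adjusted p = 0.053). Immediate early genes did not pass (adjusted p = 0.40), though EGR1 fell by 1.10 ± 0.062. In all 949 genes were higher and 583 lower (limma). Camera gave adjusted p = 4.4e-10 (range 2.3e-12 to 1.2e-09), adjusted p = 0.44 with an estimated correlation for p53 targets, adjusted p = 0.027 (range 0.0061 to 0.13), adjusted p = 0.24 with an estimated correlation for NF-kB targets, adjusted p = 0.0025 (range 0.00046 to 0.022), adjusted p = 0.24 with an estimated correlation for interferon response and adjusted p = 6.6e-05 (range 6.4e-06 to 0.00018), adjusted p = 0.58 with an estimated correlation for G2/M and mitosis. With zeros taken as missing the NF-kB list no longer passed (adjusted p = 0.129).

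After protons, MCF7 raised p53 targets and lowered mitotic and replication genes. FAS, a death receptor, rose by 1.99 ± 0.21 log2 (3.97-fold, n = 2), GDF15 by 1.90 ± 0.27 (arrays 2.65 and 1.16) and CDKN1A by 1.36 ± 0.17 (arrays 1.83 and 0.89). The standard deviation of these 2 arrays was 1.06 for GDF15 and 0.66 for CDKN1A, against 0.061 and 0.033 in MCF10A after protons. NEK2, a centrosome kinase, fell by 0.91 ± 0.079, KIF20A, a cytokinesis motor, by 0.89 ± 0.060 and XRCC2, a RAD51 paralogue, by 0.90 ± 0.12. PMCH, a neuropeptide precursor (-1.52 ± 0.25), and TAT, a tyrosine-degrading enzyme (-1.43 ± 0.21, another probe at 0.34), had the lowest ratios, not called with array weights. MDM2 (1.01 ± 0.21) was no longer called without array 1 (0.43), nor were the high ratios of EBI3, a cytokine subunit (2.71 ± 0.87; 0.38), and OR4C15, an olfactory receptor (2.56 ± 0.81; 0.36).

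Here 23 of 34 p53 targets rose and none fell, 24 of 30 G2/M and mitosis genes fell, and 16 of 30 DNA replication and 10 of 20 homologous recombination genes fell. NF-kB targets had 4 of 13 higher, among them LIF (1.22 ± 0.16), with 5 when adjusted over the list alone. RRM2 (-0.92 ± 0.23) was not called without array 1 (-0.28), and LIF not with the mean of its probes (0.39). Immediate early genes did not pass (adjusted p = 0.12), and JUNB, an AP-1 subunit, rose by 0.78 ± 0.066. By limma 647 genes were higher and 452 lower. Camera gave adjusted p = 1.9e-13 (range 4.7e-23 to 7.2e-11), adjusted p = 0.43 with an estimated correlation for p53 targets, adjusted p = 8.9e-18 (range 4.8e-23 to 1.8e-13), adjusted p = 0.42 with an estimated correlation for G2/M and mitosis, adjusted p = 1.1e-07 (range 1.9e-21 to 5.7e-06), adjusted p = 0.45 with an estimated correlation for DNA replication, adjusted p = 1.3e-06 (range 2.3e-16 to 3.3e-05), adjusted p = 0.45 with an estimated correlation for homologous recombination and adjusted p = 0.0037 (range 0.00018 to 0.031), adjusted p = 0.42 with an estimated correlation for NF-kB targets. The 2 arrays differed in the size of the response: without array 1, 617 genes were called, and without array 2, 1881. With only the groups compared in the fit 0 genes passed limma, with 4512 at an unadjusted p below 0.05, and array weights left 548.

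After protons, MDA-MB-231 changed more genes than the other lines did after protons, with NF-kB targets and inflammatory cytokines rising and histones falling. CXCL1 rose by 2.28 ± 0.21 log2 (4.84-fold, n = 2), CXCL2 by 1.79 ± 0.092 and SPARC, a matrix glycoprotein, by 1.42 ± 0.089. ECSCR, an endothelial chemotaxis receptor (3.70 ± 0.069), and COL11A1, a fibrillar collagen (3.11 ± 0.11), had the highest ratios. The AP-1 genes FOS (-2.76 ± 0.095) and FOSB (-2.33 ± 0.083) and CYP4X1, a cytochrome (-2.46 ± 0.38), were among the lowest, although a second CYP4X1 probe stood at 0. H4C8 fell by 1.09 ± 0.048 and H3C10, for histone H3, by 0.95 ± 0.11. ASPM and CENPF, proteins of the spindle pole and kinetochore, rose by 1.02 ± 0.086 and 0.83 ± 0.081, CENPF not by call with the mean of its probes (0.50). A second ASPM probe stood at 0.16 and a second CENPF probe at 0.17. With only the groups compared in the fit CYP4X1 was not called.

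NF-kB targets had 13 of 20 higher and none lower (14 when adjusted over the list alone), histone genes 5 of 16 lower, interferon response 6 higher and G2/M and mitosis 3 higher. Matrix remodelling had 8 genes higher and 1 lower, and immediate early genes 3 lower. CDKN1A (-0.070 ± 0.17), MDM2 (-0.41, another probe at 0.84) and GDF15 (0.61, arrays at 0.64 and 0.58) were not called. The p53 targets had 4 of 33 higher and 1 lower (adjusted p = 0.47), with TP53INP1 (0.98 ± 0.18) and the antiviral gene TRIM22 (1.23 ± 0.16, not called with only the groups compared) among the 4. By limma 2634 genes were higher and 1419 lower. Camera gave adjusted p = 4.3e-06 (range 1.7e-07 to 8.0e-05), adjusted p = 0.026 with an estimated correlation for NF-kB targets and adjusted p = 2.4e-05 (range 3.2e-06 to 0.00036), adjusted p = 0.026 with an estimated correlation for histones. Interferon response had adjusted p = 0.0056 (range 0.00074 to 0.019), adjusted p = 0.19 with an estimated correlation, G2/M and mitosis adjusted p = 0.0074 (range 0.00085 to 0.047), adjusted p = 0.79 with an estimated correlation, matrix remodelling adjusted p = 0.049 (range 0.018 to 0.13), adjusted p = 0.27 with an estimated correlation and immediate early genes adjusted p = 0.025 (range 0.0098 to 0.069), adjusted p = 0.55 with an estimated correlation, the last not passing without array 2 (adjusted p = 0.0692).

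**Figure D2:**
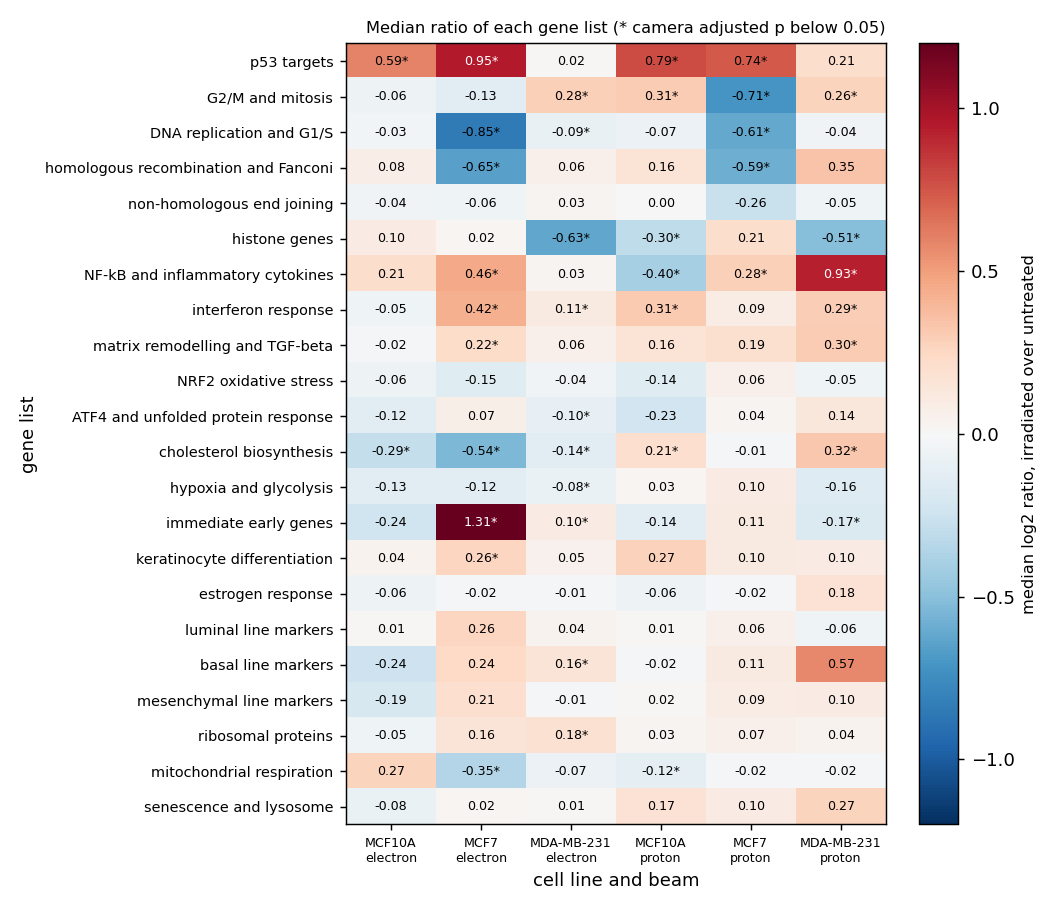
Median log2 ratio (irradiated over untreated) of each gene list (vertical axis) by line and beam (horizontal axis), 2 arrays each; an asterisk marks a camera adjusted p below 0.05 and grey a list not tested. Electron values are from scanner signals and proton values from the deposited ratio table; p53 targets are high in MCF10A and MCF7 only, while cholesterol synthesis in MCF10A and mitochondrial respiration in MCF7 after electrons, and DNA replication, ATF4 and hypoxia targets in MDA-MB-231 after electrons, turn direction with median centring.

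In MCF10A the 2 beams shared a p53 response and differed in mitotic, interferon and sterol genes and, unless zeros were taken as missing, in NF-kB targets. With both beams read from the deposited table, 348 genes were higher after both (156.7 expected by chance), 200 were lower after both (77.0 expected), and 21 p53 targets were higher after both. CXCL1 was higher after electrons than after protons by 2.07 ± 0.28 log2, with means of 0.75 ± 0.040 and -1.33 ± 0.017 (± standard deviation, n = 2 and 2). CDC20, which activates the anaphase complex, was lower after electrons by 1.07 ± 0.070 and MSMO1 by 1.81 ± 0.064, while H2BC5 was higher by 3.18 ± 0.16, with means of 2.21 ± 0.084 and -0.97 ± 0.011, and 1.3e-06 as its adjusted p, though a second probe stood at 0.11. MIXL1, a homeobox factor (-3.30 ± 0.42), SERPINB7, a protease inhibitor (-3.39 ± 0.23), and CD24, a surface glycoprotein (-3.00 ± 0.085), were among the genes most in favour of protons. In the other direction stood WNT6 (5.12 ± 0.13) and OTUD7A, a deubiquitinase (5.28 ± 0.091), whose second probe was at 0.060, both read from probes of high GC content (76.7% and 83.3%).

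The tested difference held 2920 genes higher and 2547 lower after electrons in MCF10A (limma). G2/M and mitosis had 11 of 30 lower after electrons at adjusted p = 0.0088 (range 0.0018 to 0.016), adjusted p = 0.85 with an estimated correlation, interferon response 10 of 24 lower at adjusted p = 0.0036 (range 0.00057 to 0.011), adjusted p = 0.19 with an estimated correlation and cholesterol synthesis 6 of 17 lower at adjusted p = 0.0013 (range 0.00013 to 0.0021), adjusted p = 0.11 with an estimated correlation. NF-kB targets had 11 of 17 higher after electrons at adjusted p = 0.013 (range 0.0020 to 0.079), adjusted p = 0.22 with an estimated correlation, a call lost with zeros taken as missing (adjusted p = 0.0795), mitochondrial respiration 7 of 18 higher and 1 lower at adjusted p = 0.035 (range 0.0085 to 0.098), adjusted p = 0.66 with an estimated correlation and histones 3 of 15 higher at adjusted p = 0.0088 (range 0.00098 to 0.020), adjusted p = 0.15 with an estimated correlation. p53 targets did not pass as a list (6 higher, 5 lower, 10 called over the list alone, adjusted p = 0.82), although MDM2 was higher after electrons by 1.604 ± 0.29, not called with quantile normalization (0.19), and CDKN1A did not differ by call (-0.17 ± 0.24, adjusted p = 0.56).

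In MCF7 the beams again shared p53 targets, and electrons went further in early, interferon and inflammatory genes. Both beams raised 287 genes (100.9 expected) and lowered 189 (67.7 expected), with 21 p53 targets among the raised. EGR4 was higher after electrons by 3.37 ± 0.36 log2 (means 3.35 ± 0.15 and -0.017 ± 0.69, ± standard deviation, n = 2 and 2), and S100A9 and S100A8, calcium-binding alarmins, by 3.55 ± 0.13 and 3.39 ± 0.48. IFIT2, an antiviral effector, was higher by 1.87 ± 0.088 and the mitotic genes KIF20A and NEK2 by 1.53 ± 0.084 and 1.502 ± 0.11. MAPK4 was lower after electrons (-3.77 ± 0.15, means -3.04 ± 0.0036 and 0.73 ± 0.35), as was MSMO1 (-2.45 ± 0.066, another probe at -0.65).

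After electrons 3054 genes were higher and 3067 lower than after protons in MCF7 (limma). Interferon response had 20 of 27 higher at adjusted p = 1.9e-06 (range 2.3e-08 to 7.2e-06), adjusted p = 0.13 with an estimated correlation, immediate early genes 12 of 16 higher at adjusted p = 3.8e-06 (range 3.7e-08 to 4.4e-05), adjusted p = 0.21 with an estimated correlation, G2/M and mitosis 14 of 30 higher at adjusted p = 3.6e-05 (range 1.3e-10 to 0.00069), adjusted p = 0.62 with an estimated correlation and NF-kB targets 9 of 13 higher at adjusted p = 0.00052 (range 8.6e-05 to 0.0035), adjusted p = 0.17 with an estimated correlation. Lower after electrons were 8 of 17 cholesterol genes at adjusted p = 0.0030 (range 0.00052 to 0.0078), adjusted p = 0.13 with an estimated correlation and 6 of 18 mitochondrial respiration genes at adjusted p = 0.00027 (range 1.5e-05 to 0.0013), adjusted p = 0.21 with an estimated correlation. DNA replication had 6 lower and 1 higher, and 5 over the list alone, at adjusted p = 0.041 (range 4.7e-10 to 0.97), adjusted p = 0.73 with an estimated correlation. It turned direction with quantile normalization (adjusted p = 0.933) and lost its call without proton array 2 (adjusted p = 0.967). p53 targets did not pass (9 higher, 1 lower, 7 over the list alone, adjusted p = 0.23), nor did CDKN1A (0.083 ± 0.24, adjusted p = 0.79).

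In MDA-MB-231 the beams differed most clearly in single genes such as FOSB, FOS and CXCL1 and in cholesterol synthesis. FOSB was higher after electrons by 4.43 ± 0.12 log2, with means of 2.11 ± 0.12 and -2.33 ± 0.0025 (± standard deviation, n = 2 and 2), FOS by 3.74 ± 0.13 (means 0.98 ± 0.077 and -2.76 ± 0.041) and HES1 by 2.71 ± 0.11. CXCL1 was lower by 2.52 ± 0.29 (means -0.25 ± 0.11 and 2.28 ± 0.27) and CXCL2 by 1.53 ± 0.13. ECSCR (-2.66 ± 0.097) and NPR3, a natriuretic peptide receptor (-2.47 ± 0.15), were also lower after electrons, although another NPR3 probe stood at 0.35. HMGCS1, an enzyme of cholesterol synthesis, was lower by 0.99 ± 0.059. Both beams raised 358 genes (103.4 expected) and lowered 214 (51.2 expected), with 2 p53 targets among the raised.

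After electrons 1512 genes were higher and 2054 lower than after protons in MDA-MB-231 (limma). Cholesterol synthesis had 7 of 18 lower at adjusted p = 3.0e-06 (range 1.1e-07 to 6.2e-05), adjusted p = 0.028 with an estimated correlation and was the 1 beam difference that passed with an estimated correlation. NF-kB targets had 10 of 20 lower and 1 higher, 11 over the list alone at adjusted p = 0.015 (range 0.0028 to 0.091), adjusted p = 0.12 with an estimated correlation, a call lost with zeros taken as missing (adjusted p = 0.0913). ATF4 and unfolded protein targets had 5 of 17 lower and 1 higher, 6 over the list alone at adjusted p = 0.015 (range 0.0037 to 0.31), adjusted p = 0.12 with an estimated correlation, lost with the mean of probes (adjusted p = 0.307). Histones had 3 lower at adjusted p = 0.024 (range 0.0036 to 0.053), adjusted p = 0.12 with an estimated correlation, lost without proton array 2 (adjusted p = 0.0533). Immediate early genes had 6 of 15 higher without passing (adjusted p = 0.13), and CDKN1A did not differ by call (0.037 ± 0.25, adjusted p = 0.92).

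Untreated RNA may have been shared between the beams, which is not stated, and a shared reference would account for part of the overlap. Correlation of the 2 beams over genes was 0.191 in MCF10A, 0.215 in MCF7 and 0.308 in MDA-MB-231. Over 25502 genes tested in any line it was 0.181, 0.197 and 0.327. Pairs of groups from different lines ran from -0.110 (MCF7 electrons, MDA-MB-231 protons) to 0.385 (MDA-MB-231 electrons, MCF10A protons). Such correlation was therefore not particular to the beams of a line. The dyes were not swapped, so a dye bias could also raise the overlap, which was not tested. Beam and experimental batch cannot be told apart, so a difference between beams may belong to either. Counts of beam differences also follow the deposited table, which called more genes after electrons than the scanner signals did.

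**Figure D3:**
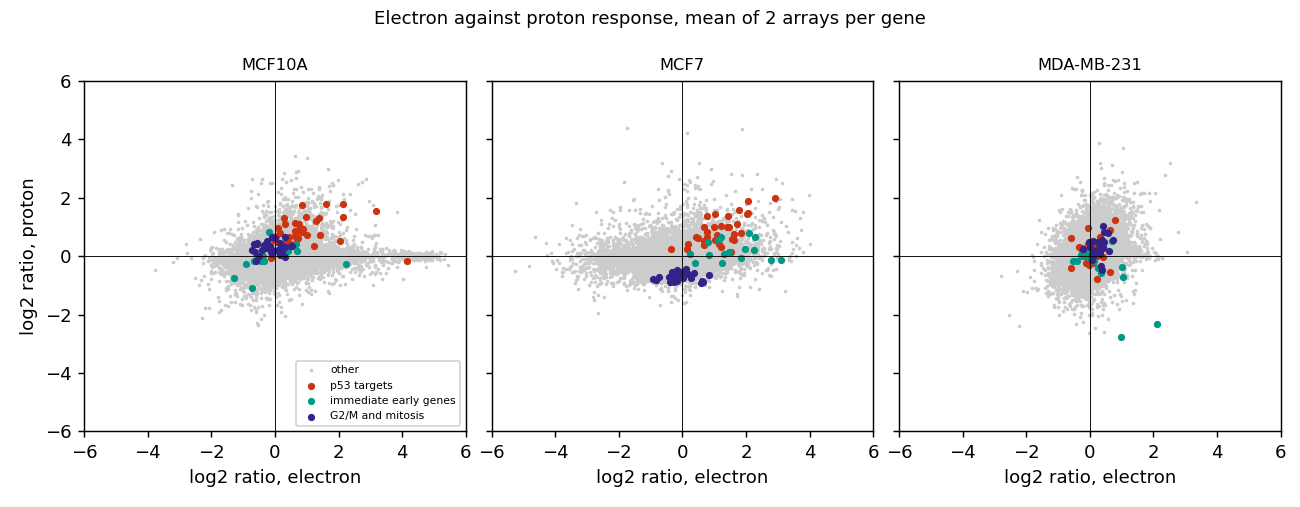
Log2 ratio (irradiated over untreated) after protons against that after electrons, both from the deposited table, 1 point per tested gene as the mean of 2 arrays per beam, in each line. p53 targets (red) lie high on both axes in MCF10A and MCF7, G2/M genes (dark blue) lie low only after protons in MCF7, and a band of MCF10A genes is high after electrons alone.

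After electrons MCF7 differed from MCF10A in early, replication and interferon genes. EGR2 responded more strongly in MCF7 by 2.85 ± 0.049 log2 (responses 2.77 ± 0.067 and -0.079 ± 0.045, ± standard deviation, n = 2 and 2), EGR4 by 2.52 ± 0.056 and CAV1, the caveolar coat protein, by 2.73 ± 0.042. CDC45 and RRM2 had lower responses by 2.05 ± 0.046 and 1.74 ± 0.051, and FANCA by 1.40 ± 0.063. BST2, an antiviral tetherin, was higher by 1.93 ± 0.13 and IFIT1 by 2.07 ± 0.083. WNT6 (-4.59 ± 0.14), MEX3D, an RNA-binding ligase (-4.56 ± 0.14), and COX6A2 (-4.43 ± 0.099) were among the lowest relative to MCF10A, with other probes of WNT6 and MEX3D at 0.76 and 0.060; WNT6 and COX6A2 are among the 151 genes whose rise on the MCF10A electron arrays may be technical. With scale normalization CAV1 (2.54), BST2 (1.66), CDC45 (-1.51) and the last 3 genes were not called.

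Limma called 1510 genes higher and 2370 lower in MCF7. In all, 539 were called with scale normalization and 8690 with processed signals. Immediate early genes had 13 of 16 higher and 1 lower at adjusted p = 2.9e-07 (range 5.5e-09 to 0.00057), adjusted p = 0.12 with an estimated correlation, interferon response 12 of 28 higher at adjusted p = 1.2e-07 (range 3.9e-09 to 1.0e-05), adjusted p = 0.23 with an estimated correlation, DNA replication 18 of 30 lower at adjusted p = 2.3e-08 (range 2.5e-11 to 0.0028), adjusted p = 0.12 with an estimated correlation and homologous recombination 12 of 20 lower at adjusted p = 4.4e-07 (range 3.6e-09 to 0.0041), adjusted p = 0.29 with an estimated correlation. Mitochondrial respiration had 10 of 17 lower at adjusted p = 0.00014 (range 5.5e-06 to 0.23), adjusted p = 0.37 with an estimated correlation. p53 targets had 13 of 35 higher and 2 lower at adjusted p = 0.0065 (range 0.0012 to 0.72), adjusted p = 0.62 with an estimated correlation, a difference that turned direction with scale normalization (adjusted p = 0.724). CDKN1A did not differ by call (-0.16 ± 0.064). Line and slide cannot be told apart here, since each line had its own slides and scan day.

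Against MCF10A, the electron response of MDA-MB-231 was lower in p53 targets. GDF15 was lower by 2.50 ± 0.075 log2 (responses -0.44 ± 0.054 and 2.07 ± 0.035, ± standard deviation, n = 2 and 2) and CDKN1A by 1.54 ± 0.063. H2BC5 and H4C8 were lower by 2.59 ± 0.17 and 1.84 ± 0.065, with a second H2BC5 probe at -0.49. EEF1A1 was higher by 1.89 ± 0.037, FOS by 1.69 ± 0.065, IDH1, a dehydrogenase that yields NADPH, by 1.58 ± 0.10 and the mitotic genes TOP2A and CDC20 by 0.96 ± 0.046 and 0.89 ± 0.049. COX6A2 (-4.34 ± 0.098), IFITM5, a bone membrane protein (-4.11 ± 0.084), and SOX3 (-4.05 ± 0.11) were among the lowest, another SOX3 probe being at 0.080; COX6A2 and SOX3 are among the 151 genes whose rise on the MCF10A electron arrays may be technical. With scale normalization GDF15 (-4.61), CDKN1A (-2.64), FOS, IDH1, EEF1A1 and the last 3 genes were not called, and with median centring EEF1A1 (1.12), TOP2A (0.78) and CDC20 (0.66).

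Limma called 629 genes higher and 1385 lower, and with median centring 31 higher and 902 lower. p53 targets had 17 of 35 lower at adjusted p = 1.2e-10 (range 1.2e-16 to 0.00027), adjusted p = 0.53 with an estimated correlation, histones 7 of 16 lower at adjusted p = 4.2e-09 (range 5.6e-11 to 1.8e-06), adjusted p = 0.23 with an estimated correlation and G2/M and mitosis 5 higher at adjusted p = 4.9e-06 (range 4.4e-07 to 0.018), adjusted p = 0.23 with an estimated correlation. Immediate early genes had 6 of 15 higher and 2 lower at adjusted p = 0.0049 (range 0.0019 to 0.14), adjusted p = 0.23 with an estimated correlation, and interferon response 2 higher at adjusted p = 5.9e-05 (range 1.4e-07 to 0.043), adjusted p = 0.24 with an estimated correlation.

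Against MCF7, the electron response of MDA-MB-231 was lower in p53 and early genes and higher in replication genes. GDF15 was lower by 2.62 ± 0.075 log2 (responses -0.44 ± 0.054 and 2.18 ± 0.16, ± standard deviation, n = 2 and 2), EGR2 by 2.70 ± 0.047 and CDKN1A by 1.38 ± 0.063. RRM2 was higher by 1.84 ± 0.050, FEN1, the flap nuclease of lagging strands, by 1.35 ± 0.044 and BRCA1 by 1.32 ± 0.037. H2AC18, for histone H2A, was lower by 2.15 ± 0.28. MAPK4 (2.79 ± 0.042), AOX1, an aldehyde oxidase (2.51 ± 0.049), and ZNF652 (2.50 ± 0.088) were among the highest relative to MCF7, and TNFRSF11B, a decoy receptor (-2.62 ± 0.043), was among the lowest. With scale normalization GDF15 (-1.99) and CDKN1A (-0.62) were not called.

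Limma called 1686 genes higher and 1372 lower, but 868 and 1813 with median centring. p53 targets had 24 of 35 lower and 1 higher at adjusted p = 8.2e-13 (range 7.4e-15 to 0.00026), adjusted p = 0.29 with an estimated correlation, immediate early genes 14 of 16 lower at adjusted p = 1.4e-09 (range 4.4e-11 to 0.27), adjusted p = 0.10 with an estimated correlation, DNA replication 19 of 30 higher at adjusted p = 1.4e-09 (range 3.4e-11 to 0.28), adjusted p = 0.10 with an estimated correlation and homologous recombination 14 of 20 higher at adjusted p = 4.6e-08 (range 1.5e-09 to 0.0012), adjusted p = 0.22 with an estimated correlation. Histones had 8 of 16 lower at adjusted p = 1.1e-06 (range 3.9e-09 to 1.1e-05), adjusted p = 0.22 with an estimated correlation. Interferon response had 9 of 29 lower at adjusted p = 6.6e-05 (range 1.9e-05 to 0.61), adjusted p = 0.22 with an estimated correlation, a difference that turned direction with scale normalization (adjusted p = 0.615). Genes of G2/M and mitosis had 7 higher at adjusted p = 4.9e-05 (range 6.2e-06 to 0.0054), adjusted p = 0.16 with an estimated correlation.

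After protons MCF7 differed from MCF10A in mitotic genes and NF-kB targets. NEK2 was lower in MCF7 by 1.26 ± 0.11 log2 (responses -0.91 ± 0.28 and 0.35 ± 0.038, ± standard deviation, n = 2 and 2) and CENPF by 1.24 ± 0.11. BIRC3, an inhibitor of apoptosis, was higher by 1.34 ± 0.088, PPARGC1A by 2.88 ± 0.10 and PTX3, a soluble pattern receptor, by 2.80 ± 0.079. IVL (-3.71 ± 0.48), INSL4 (-3.15 ± 0.19) and APOBEC3B (-3.35 ± 0.30) were among the lowest. FANCD2, a crosslink repair protein, was lower as well (-1.25 ± 0.14), though not by call with only the groups compared. Limma called 910 genes higher and 1222 lower. With only the groups compared 1024 were called.

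Of the G2/M and mitosis genes 29 of 30 were lower, 30 over the list alone at adjusted p = 4.8e-18 (range 2.2e-24 to 2.7e-12), adjusted p = 0.30 with an estimated correlation, homologous recombination 9 lower, 12 over the list alone at adjusted p = 9.4e-05 (range 1.6e-15 to 0.0016), adjusted p = 0.51 with an estimated correlation, and NF-kB targets 11 of 21 higher at adjusted p = 0.00057 (range 4.7e-05 to 0.0032), adjusted p = 0.16 with an estimated correlation. DNA replication had 4 lower, 3 over the list alone at adjusted p = 0.0012 (range 4.9e-18 to 0.56), adjusted p = 0.72 with an estimated correlation, and without MCF7 array 1 did not pass (adjusted p = 0.562). p53 targets did not pass (3 higher, 3 lower, 6 over the list alone, adjusted p = 0.74), nor did CDKN1A (-0.43 ± 0.25).

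Against MCF10A, the proton response of MDA-MB-231 had lower p53 targets and higher NF-kB targets. CXCL1 was higher by 3.60 ± 0.29 log2 (responses 2.28 ± 0.27 and -1.33 ± 0.017, ± standard deviation, n = 2 and 2) and CXCL2 by 2.71 ± 0.13. CDKN1A was lower by 1.87 ± 0.25 and MDM2 by 1.97 ± 0.30. IVL (-4.24 ± 0.48), IGFL2 (-3.98 ± 0.32), APOBEC3B (-3.03 ± 0.30) and KLK7 (-2.81 ± 0.53) were lowest relative to MCF10A. SPARC was higher by 1.80 ± 0.13 and LOX, which crosslinks collagen, by 1.58 ± 0.054. Limma called 2390 genes higher and 1980 lower. p53 targets had 16 of 35 lower at adjusted p = 8.9e-06 (range 1.7e-08 to 0.00011), adjusted p = 0.82 with an estimated correlation, NF-kB targets 14 of 22 higher and 1 lower, 16 over the list alone at adjusted p = 2.8e-08 (range 1.0e-09 to 2.6e-05), adjusted p = 0.031 with an estimated correlation, and ATF4 and unfolded protein targets 7 of 17 higher and 1 lower, 9 over the list alone at adjusted p = 0.00040 (range 3.2e-05 to 0.010), adjusted p = 0.053 with an estimated correlation.

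Against MCF7, the proton response of MDA-MB-231 had lower p53 targets, higher mitotic genes and lower histones. CDKN1A was lower by 1.43 ± 0.25 log2 (responses -0.070 ± 0.047 and 1.36 ± 0.66, ± standard deviation, n = 2 and 2), FOSB by 2.99 ± 0.12 and FOS by 2.89 ± 0.13. ASPM and CENPF were higher by 1.59 ± 0.12 and 1.43 ± 0.12, XRCC2 by 1.56 ± 0.17 and CXCL1 by 2.28 ± 0.29. H4C8 was lower by 1.18 ± 0.069. COL8A2, a network collagen, was among the highest (3.07 ± 0.15) and EPHA2, a receptor kinase, among the lowest (-2.52 ± 0.14). With only the groups compared CDKN1A (adjusted p = 0.102), ASPM, CENPF and XRCC2 were not called. Limma called 2203 genes higher and 1495 lower. With only the groups compared 719 were called.

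Among G2/M and mitosis genes 27 of 30 were higher, 28 over the list alone at adjusted p = 2.2e-14 (range 1.8e-20 to 8.8e-11), adjusted p = 0.34 with an estimated correlation, homologous recombination 14 higher, 15 over the list alone at adjusted p = 1.4e-05 (range 7.4e-15 to 0.00026), adjusted p = 0.45 with an estimated correlation, and histones 10 of 16 lower and 1 higher, 11 over the list alone at adjusted p = 8.5e-07 (range 7.7e-08 to 7.5e-06), adjusted p = 0.028 with an estimated correlation. p53 targets had 15 lower, 17 over the list alone at adjusted p = 1.8e-07 (range 1.8e-19 to 3.8e-06), adjusted p = 0.45 with an estimated correlation, and immediate early genes 7 of 16 lower at adjusted p = 0.0033 (range 5.1e-05 to 0.016), adjusted p = 0.39 with an estimated correlation. DNA replication had 7 higher at adjusted p = 0.0011 (range 6.2e-17 to 0.20), adjusted p = 0.60 with an estimated correlation and without MCF7 array 1 did not pass (adjusted p = 0.198).

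**Figure D4:**
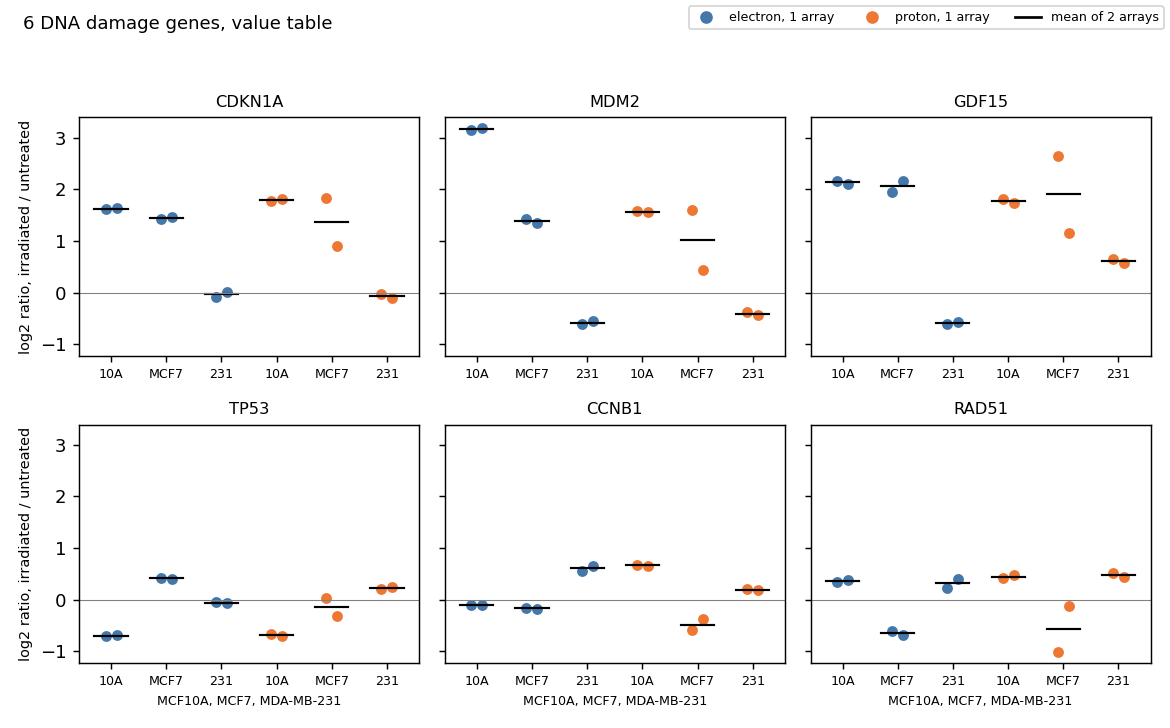
Log2 ratio (irradiated over untreated, deposited table for both beams) of 6 DNA damage genes by line, 1 point per array and a bar at the mean of 2 arrays. CDKN1A is high in MCF10A and MCF7 after either beam and near 0 in MDA-MB-231, and the 2 MCF7 proton arrays stand apart for CDKN1A, MDM2, GDF15 and RAD51.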

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

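All differences between groups that passed were compared with the simplest view, that the groups respond alike. Beams differed in 5467 of 19006 tested genes in MCF10A, 6121 of 21164 in MCF7 and 3566 of 24017 in MDA-MB-231. These counts rest on the deposited table, where electron effects alone called 5648, 6470 and 1810 genes. From scanner signals electron effects called 1654, 2865 and 254, so the beam counts depend on the source of the ratios. Electron responses of lines differed in 3880 genes (MCF7 and MCF10A), 2014 (MDA-MB-231 and MCF10A) and 3058 (MDA-MB-231 and MCF7), and proton responses in 2132, 4370 and 3698. Among genes called in both groups some went opposite ways: 21, 37 and 22 between beams with electron calls from scanner signals and proton calls from the table, 69, 51 and 14 between lines after electrons, and 37, 60 and 45 between lines after protons. With the table for both beams, genes higher after electrons and lower after protons were 74 in MCF10A (96.3 expected by chance), 39 in MCF7 (70.5 expected) and 51 in MDA-MB-231 (55.7 expected), and the reverse 41 (125.3 expected), 111 (96.9 expected) and 69 (95.1 expected). Of the 51 electron differences between MDA-MB-231 and MCF10A 49 were lower in MDA-MB-231.

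Named genes moved in opposite ways in 28 differences. Between beams, electron minus proton, these were CXCL1 (2.07), H2BC5 (3.18) and LMNB1 (2.45) in MCF10A, HMGB2 (1.51) and MAPK4 (-3.77) in MCF7, and FOS (3.74), FOSB (4.43) and HES1 (2.71) in MDA-MB-231. Group means of HES1 in the table were 1.40 ± 0.071 and -1.31 ± 0.081 (± standard deviation, n = 2 and 2). Between MCF7 and MCF10A after electrons they were BST2 (1.93), CAV1 (2.73), KRT8 (1.87) and LMNB1 (-2.78). After protons they were BIRC3 (1.34), CENPF (-1.24) and PPARGC1A (2.88).

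Between MDA-MB-231 and MCF10A the electron responses of FOS (1.69) and H2BC5 (-2.59) ran opposite, as did the proton responses of CXCL1 (3.60), CXCL2 (2.71), EGLN3 (-1.60), LMNB1 (1.25), LOX (1.58) and SLC7A11 (1.78). Between MDA-MB-231 and MCF7 the electron response of H2AC18 (-2.15) and the proton responses of CENPF (1.43), FOSB (-2.99), LMNB1 (1.42) and XRCC2 (1.56) did.

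The tests in this paragraph were written down before they were run and chosen after the pattern was seen. Intervals in parentheses are over genes or probes and do not cover the spread between arrays. The same holds for the tests of the MDA-MB-231 electron arrays and the MCF7 proton arrays below. On the MCF10A electron arrays 151 genes were over 8-fold higher. Their probes had a GC content 31.7 percentage points above that of all tested genes (30 to 31.7; their median was 75.0), so probe chemistry could explain them. A dim untreated channel is excluded: 0% of them (0% to 2.41%) were not well above background in Cy3, against 6.89% of all genes. Nor did these genes show a response common to both beams: their median on the MCF10A proton arrays was 0.016 (0.0045 to 0.036). Whether dim spots hold that median near 0 cannot be checked there. After electrons the median of these genes was 3.98 in MCF10A, 0.28 in MCF7 and 0.54 in MDA-MB-231. In each line 100% of them were well above background in both dyes. This argues against a response to electrons of that size common to the 3 lines. All lines were read with the same probes, so GC content alone does not account for the difference between lines. A response to electrons in MCF10A alone was not tested. Without genes over 60% GC 1381 genes were still called.

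These tests were also chosen after the pattern was seen. Ratios of the MDA-MB-231 electron arrays correlated with the 3 proton groups (mean r 0.334) more than with the other electron groups (0.145). With trends in GC content and in the mean intensity of the electron arrays removed the mean was 0.347 (0.338 to 0.357 over resampled genes). On these arrays those trends do not account for it, and the spread between arrays was not covered. Intensities of the proton arrays are missing, so a trend with intensity on those arrays was not tested. Without the cell cycle lists it was 0.335 (0.323 to 0.345), but only 25406 of 25502 genes were left to show a change, so this excludes nothing about the cell cycle. A shared batch and a shared biology remain open and may not be separable here.

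The random noise test below was written after the values were seen, and the spike-in test after the pattern was. The 2 MCF7 proton arrays differed in the size of the response: p53 targets had medians of 1.12 and 0.42 (slope 0.526, 0.424 to 0.629). A slope above 0 argues against random noise alone for that list. It does not exclude noise, since the test was chosen with these values known. Its interval also takes 34 genes of 1 pair of arrays as independent. For DNA replication the slope was 0.382 (0.244 to 0.520). For G2/M and mitosis it was 0.128 (-0.087 to 0.344), an interval that holds 0, although the list median on array 2 was -0.50. How single genes of that list rank may therefore be noise. Spike-in probes had a slope of 1.01 (0.998 to 1.02), which excludes compression of the whole array. A weaker response of these cells or mixed RNA could be the cause and was not tested.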

How the results depend on the processing

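Of the counts of genes 63 moved by over 1.5 times and 187 did not. Over the alternatives, calls of lists were kept 1615 times, lost 233 times and turned 11 times, and gained 236 times by lists not called before; calls of named genes were kept 7628 times, gained 31 times, lost 543 times (126 with scale normalization, 123 at 2-fold, 68 with only the groups compared, 45 with median centring, 32 with the mean of probes) and turned 10 times. Signal over background limits what can be read of dim genes: electron arrays had 55.9% to 73.1% of spots well above background in Cy3, and for protons the measure is missing.

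Genes called after electrons in MCF10A (1654; 1110 higher, 544 lower): processed signals 5642 (3117 and 2525), median centring 5050 (5019 and 31), scale normalization 305 (277 and 28), no fold minimum 11288, 2-fold 566, deposited ratios 5648 (3139 and 2509), 1 array left out 1319 to 2119. In MCF7 (2865; 1259 and 1606): processed signals 6440, median centring 5715 (4989 and 726), scale normalization 369 (123 and 246), no fold minimum 14948, 2-fold 740, deposited ratios 6470, 1 array left out 2862 to 2887. In MDA-MB-231 (254; 105 and 149): no background correction 532, processed signals 1805 (934 and 871), median centring 0 (limma, 5225 at unadjusted p below 0.05), scale normalization 1440 (850 and 590), mean of probes 167, no fold minimum 6440, 2-fold 19, deposited ratios 1810 (943 and 867), 1 array left out 252 to 268. With median centring the median ratio was 0.27 in MCF10A and 0.20 in MCF7, against 0.014 and 0.015. Scaling assumptions therefore set the balance of higher and lower genes.

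After protons in MCF10A (1532): no filter on dim genes 3489, no fold minimum 8867, 2-fold 482, 1 array left out 1325 to 1352. In MCF7 (1099): no filter 1836, quantile normalization 2200, only the groups compared 0 (limma, 4512 at unadjusted p below 0.05), no fold minimum 7242, 2-fold 266, array weights 548, 1 array left out 617 to 1881. In MDA-MB-231 (4053): no fold minimum 12886, 2-fold 1182, 1 array left out 3626 to 3863. A group left with a lone array takes its spread from the other groups.

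Beam differences without a fold minimum and at 2-fold were 11477 and 2400 in MCF10A (5467), 12368 and 2736 in MCF7 (6121), and 9456 and 1205 in MDA-MB-231 (3566), and with 1 array left out 5147 to 5294, 5620 to 6190 and 3078 to 3639. Electron line differences, MCF7 and MCF10A (3880; 1510 and 2370): processed signals 8690 (4276 and 4414), scale normalization 539 (152 and 387), no fold minimum 13940, 2-fold 1310, deposited ratios 8563, 1 array left out 3642 to 4217. MDA-MB-231 and MCF10A (2014; 629 and 1385): no background correction 3046, processed signals 7365 (3708 and 3657), median centring 933 (31 and 902), scale normalization 1689 (786 and 903), no fold minimum 9741, 2-fold 717, deposited ratios 6996 (3322 and 3674), 1 array left out 1699 to 2423. MDA-MB-231 and MCF7 (3058; 1686 and 1372): processed signals 7101, median centring 2681 (868 and 1813), scale normalization 1472, no fold minimum 12970, 2-fold 783, deposited ratios 7048, 1 array left out 3021 to 3113. Proton line differences in the same order: 2132, with only the groups compared 1024, no fold minimum 6629, 2-fold 791, 1 array left out 1666 to 2692; 4370, no fold minimum 10354, 2-fold 1525, 1 array left out 3670 to 4366; 3698, only the groups compared 719, no fold minimum 9091, 2-fold 1277, 1 array left out 3275 to 4267.

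With median centring these genes turned to higher in MCF10A after electrons: PRDX1 (0.30), FTL (0.062), ENO1 (0.40), VIM (0.22) and RPL4 (0.45), and 2 turned to lower in the difference of MCF7 and MCF10A, S100A2 (-0.38) and VIM (-0.14). With the mean of probes RPS10 in MCF7 after electrons turned (-0.096), as did TAT in MCF10A after protons (0.058), and with scale normalization IFIT1 in MDA-MB-231 against MCF7 (0.54). Lists that turned, by adjusted p: with median centring cholesterol synthesis in MCF10A (0.931), mitochondrial respiration in MCF7 (0.943), DNA replication (0.343), ATF4 (0.343) and hypoxia (0.624) in MDA-MB-231, all after electrons, basal markers in MCF7 against MCF10A (0.038), and basal markers (0.023) and ribosomal proteins (0.018) in MDA-MB-231 against MCF10A; with quantile normalization DNA replication between beams in MCF7 (0.933); with scale normalization p53 targets in MCF7 against MCF10A (0.724) and interferon response in MDA-MB-231 against MCF7 after electrons (0.615). Their cause was not tested.

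Camera with an estimated correlation kept 5 of 110 list calls and lost 105; fry kept 107, lost 3, gained 138 and passed 2 more in the other direction. Replicate numbers number scans and so pair nothing; with them as a block on separate scans the beam differences were 5787, 6710 and 4600, electron line differences 3894, 2019 and 3068, and proton line differences 2979, 5539 and 5013, none moved by 1.5 times. A random block of slide or scan day could not be fitted with lines on slides of their own, and scans with the array as a random block replaced it. Dividing groups of 2 arrays further was not possible.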

Other observations

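After electrons 3 genes were higher in all 3 lines, the Notch repressor HES1, with another MDA-MB-231 probe at 0.16, the neural factor SOX1 and the zinc finger gene ZNF575, and 1 was lower, MCM6. None would be shared with median centring, where 0 genes passed limma in MDA-MB-231 although 5225 had an unadjusted p below 0.05. Genes read from probes over 70% GC had raised medians after electrons in each line: 2.09 in MCF10A, 0.23 in MCF7 and 0.30 in MDA-MB-231. Whether GC content plays a part in the shared rises was not tested. After protons 40 were higher in all, among them TP53INP1, the decoy receptor TNFRSF10C, the polyamine enzyme SAT1 and the long non-coding RNA NEAT1, and 10 were lower, among them the histone genes H4C2 and H4C4. None of those would be shared with only the groups compared, where 0 genes passed limma in MCF7, with 4512 at an unadjusted p below 0.05. These genes were picked after values were seen.

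Non-homologous end joining passed camera in no comparison, and neither did estrogen response, luminal markers or senescence, although fry passed them in several. In MCF7 after electrons estrogen response had 2 of 16 higher and 3 lower (adjusted p = 0.99), luminal markers 3 of 11 higher and 2 lower (adjusted p = 0.65) and senescence 2 higher and 2 lower of 14 (adjusted p = 0.90), while non-homologous end joining gave an adjusted p of 0.78. Hypoxia targets fell as a list in MDA-MB-231 after electrons with none called, a fall that turned into a rise with median centring, at adjusted p = 0.0087 (range 0.0037 to 0.62), adjusted p = 0.24 with an estimated correlation, and ribosomal proteins rose with none called, median 0.18, at adjusted p = 0.00072 (range 2.8e-09 to 0.37), adjusted p = 0.26 with an estimated correlation. NRF2 targets had 3 genes higher in the proton response of MCF7 than of MCF10A, at adjusted p = 0.037 (range 0.015 to 0.068), adjusted p = 0.18 with an estimated correlation. Basal markers had 4 higher in the electron response of MCF7 than of MCF10A, a difference that turned direction with median centring, at adjusted p = 0.0046 (range 0.0012 to 0.22), adjusted p = 0.24 with an estimated correlation. For a gene dim in MCF7 such a difference rests mainly on its MCF10A ratio. The basal keratin KRT5, for example, had an untreated log2 signal of 1.87 in MCF7 and 16.45 in MCF10A. Mesenchymal markers had 4 of 10 higher after electrons than protons in MCF7, at adjusted p = 0.039 (range 0.015 to 0.21), adjusted p = 0.21 with an estimated correlation. Basal markers in MDA-MB-231 after protons had 4 of 8 higher and a median of 0.57 without passing (adjusted p = 0.089). In MCF7 after electrons keratinocyte differentiation rose with 1 gene called, at adjusted p = 0.0031 (range 0.0018 to 0.13), adjusted p = 0.28 with an estimated correlation.

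The p53 targets rose in MCF10A and MCF7 with either beam, and the list did not pass in MDA-MB-231. A p53-dependent response is a hypothesis for this, and p53 activity was neither altered nor measured here. The tested line differences after protons (16 of 35 lower in MDA-MB-231 than in MCF10A) carry that reading only in part, being lost at adjusted p = 0.82 with an estimated correlation. The electron p53 call of MCF10A was lost as well, at adjusted p = 0.61 with an estimated correlation, so the reading may not hold. With so few residual degrees of freedom these losses cannot decide the question. Falling mitotic genes in MCF7 after protons, with 24 of 30 lower, could come from an arrest before mitosis, a hypothesis that DNA content by flow cytometry would test, and their tested difference from electrons (14 of 30) held without either proton array. Both were lost, at adjusted p = 0.42 and adjusted p = 0.62 with an estimated correlation, so an arrest is only a possible reading. Cell counts or protein were not analysed here, so arrest, death and repair could not be read from these arrays.

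In MDA-MB-231 histone genes fell after both beams, and the list fell in MCF10A after protons too (adjusted p = 0.00091, adjusted p = 0.14 with an estimated correlation). Amplification from the poly(A) tail would capture mainly polyadenylated histone RNA, and the primer is not stated, so the fall could reflect processing of histone RNA or fewer cells in S phase. The proton histone call passed with an estimated correlation (adjusted p = 0.026) and the electron call did not (adjusted p = 0.21). Staining for S phase and sequencing of total RNA would separate these readings, and neither was done here.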
